A study of Homo sapiens with 12 samples.

How the data were processed

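The gene FPKM values (fragments per kilobase of gene, scaled to the mapped fragments of a library) were made by the authors: per the submitters' processing notes, reads were aligned to hg38 with TopHat, whose version is not stated, and quantified with Cufflinks 2.2.1. The deposited lncRNA table holds FPKM per assembled locus by the authors' Cufflinks run; its header does not name the unit, which the locus names and values give. The deposited miRNA counts are whole-number reads per mature miRNA as counted by the authors, with the counting tool not stated. The deposited circular RNA files hold unique read counts, and beside them values that the authors call TPM but that are RPM, counts scaled to a total given in the header, with no division by length. Long RNA was depleted of ribosomal RNA with Ribo-Zero and read as 150 bp pairs, and RNA of 18 to 30 nt was read as 50 bp single reads, both on Illumina machines, per the labels.

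R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 was used. Genes with a mean of at least 1 FPKM over 6 libraries were tested with limma (variance trend, two-sided) on log2(FPKM + 1), and lncRNA loci with a mean of at least 0.1 FPKM on log2(FPKM + 0.1). Genes that a file did not list entered as 0. The 4716 entries of the lncRNA table fold into 4650 loci whose repeated entries hold equal values. Counts of miRNAs and circular RNAs were tested with edgeR's quasi-likelihood test (robust, TMM), after filterByExpr, which for circular RNAs kept those listed in at least 3 libraries. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, with a second count at a log2 change of at least 1. Log2 changes include the added constant, so they understate genes with low values. Errors of log2 changes are standard errors; for edgeR they are the log2 change divided by the square root of F.

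Alternative scalings of the gene values were TMM, quantile normalization and median centring. Of 34 gene lists with 922 members fixed before the data were opened, 31 had at least 5 tested members. Camera used a preset correlation of 0.01, with an estimated correlation and fry beside it. Each of 7 miRNA lists was tested in the same way.

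Residuals of libraries with the same replicate number, across the groups, had correlations of 0.124, 0.298 and 0.194 for genes, 0.298, 0.246 and 0.295 for lncRNA loci and 0.412, 0.597 and 0.311 for miRNAs, and of 0.028, 0 and 0.021 for circular RNAs. For genes, co-culture replicate 3 correlated more with untreated replicate 1 (0.232) than with its own number. Replicate number was therefore also fitted as a block for the first 3 data types, and for circular RNAs as a further alternative with little ground, which leaves 2 residual degrees of freedom in place of 4.

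Genes named in the text follow a rule fixed at the same time: the 6 largest rises and the 6 largest falls among called genes without overlap of the groups and with a mean of at least 5 FPKM, the 4 most abundant called genes with a log2 change of at least 1, up to 4 called members per list with the smallest adjusted p, and a fixed set always reported. Of the genes this rule takes, 2 are not reported here. Loci follow the same pattern, with the 5 largest rises and falls and a mean of at least 0.5 FPKM, and so do miRNAs of the fit without the block. Some loci that the rule takes are not named in the text. Examples from the blocked miRNA fit were chosen after their values were seen. Circular RNAs named are those called in the main comparison or among those listed in all 6 libraries. The choice of the 12 lists whose members are named was made after exploratory values had been seen. The circular RNA comparison was added after the files were seen.

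In a self-test on simulated values with the means and spreads of the real data and known changes, limma recovered 46.3%, 77.6% and 97% of genes at 1.5-fold, 2-fold and 4-fold, with 2 false calls among 10575 unchanged genes, and edgeR recovered 36.9%, 75% and 100% of miRNAs, with 4 false calls among 273. With the block, 9%, 64.2% and 95.5% of genes and 27.7%, 73.3% and 100% of miRNAs were recovered. The simulated libraries shared no replicate effect, so the block had nothing to remove there. These shares therefore do not tell what the block does in the real data. At 4-fold, 2 of 66 lncRNA changes and 1 of 39 circular RNA changes were recovered, so few of those calls can be expected even where changes are large. False calls came to 0 among 4441 unchanged lncRNA loci and 2 among 4899 unchanged circular RNAs. With 0 circular RNA changes recovered at 1.5-fold and 2-fold, false circular RNA calls outnumbered true ones, so such calls are uncertain. Camera was tried on a separate simulation, with independent genes of equal spread, and called the list that was raised and 0 others. Genes of the real lists are correlated, so this does not measure false list calls in the real data.

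No libraries were duplicates of each other. Sequence composition, miRNA target sites and transcript lengths were left out because no genome or transcript model came with the files.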

Results

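The series measured RNA in MDA-MB-231 cells, a human triple-negative breast cancer line, that were either untreated or kept beneath Transwell inserts holding human adipose cells. Per the labels, 50000 tumour cells settled for 24 hours, and 500000 adipose cells were then added in the inserts for 36 hours. Long RNA was sequenced from 3 libraries labelled co-culture and 3 labelled untreated, and small RNA from another 3 and 3, which makes 12 libraries. The long-RNA files listed 15641 ± 107 genes (mean ± SD, n = 3) in the libraries labelled co-culture and 16337 ± 86.4 in those labelled untreated, and 14172 genes were listed in all 6. These files give normalized values without read totals, so the depth of the long-RNA libraries is unknown. The small-RNA libraries labelled co-culture held 6961518, 5752682 and 6811129 miRNA reads, and those labelled untreated held 7208615, 6634448 and 6959015. Another kind of file gave 6662 to 10565 circular RNAs per long-RNA library.

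The sample titles go with the treatment labels, since samples labelled untreated are titled WT231 and samples labelled co-culture GPY231, but the codes of the data columns point the other way. Columns of libraries labelled co-culture carry the code WT, which reads as wild type, and columns of libraries labelled untreated carry the code YD. Groups here follow the treatment labels and titles, and every direction given would turn round if the column codes alone were right.

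The main comparison asked which genes differed between tumour cells labelled co-culture and tumour cells labelled untreated. PLIN2, a coat protein of lipid droplets, was 2.87-fold lower in the libraries labelled co-culture (24.9 ± 1.66 against 73.3 ± 1.53 FPKM, mean ± SD, n = 3), and ANGPTL4, a secreted lipase inhibitor driven by PPARs, was 3.02-fold lower (3.37 ± 0.69 against 12.1 ± 1.64 FPKM). HSPA5, the main chaperone of the endoplasmic reticulum, was 2.86-fold lower (49.6 ± 3.85 against 144 ± 19.2 FPKM), and VEGFA, a hypoxia-induced angiogenic factor, was 2.10-fold lower (7.05 ± 0.414 against 16.1 ± 2.93 FPKM). Replication-dependent histone genes were higher, among them HIST1H4C, which encodes histone H4, at 3688 ± 993 against 1116 ± 350 FPKM. COX7B, a subunit of cytochrome c oxidase, was 2.47-fold higher (257 ± 43 against 103 ± 6.53 FPKM), and the ribosomal protein gene RPL9 was 2.43-fold higher (1633 ± 82.6 against 672 ± 54.9 FPKM).

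Among 10775 genes tested, limma called 6859 at an adjusted p under 0.05, with 873 higher and 5986 lower in the libraries labelled co-culture. A change of at least 2-fold was found for 1199 of them, 92 higher and 1107 lower. The median log2 change over all genes tested was −0.39, so most calls were falls on the deposited scale, and the split moved with the scaling. TMM scaling gave 2988 higher and 3447 lower, quantile normalization 2833 and 2985, and median centring 3932 and 2311. Under all 4 scalings, 818 genes were called higher and 2255 lower, while 1551 of the 6859 called genes changed sign under at least 1 scaling. The groups did not overlap for 97.2% of the called genes, which were picked by the same difference, and for 68.2% of the genes tested. Chance gives 10% for any 1 gene, but a shift shared by most genes parts many of them at once. These shares were taken on the deposited scale, so they do not tell how many genes changed apart from that shift. Changes below are log2 values, co-culture-labelled minus untreated-labelled, on the deposited scale unless TMM is named; TMM values are relative to the shift of most genes.

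**Figure D1:**
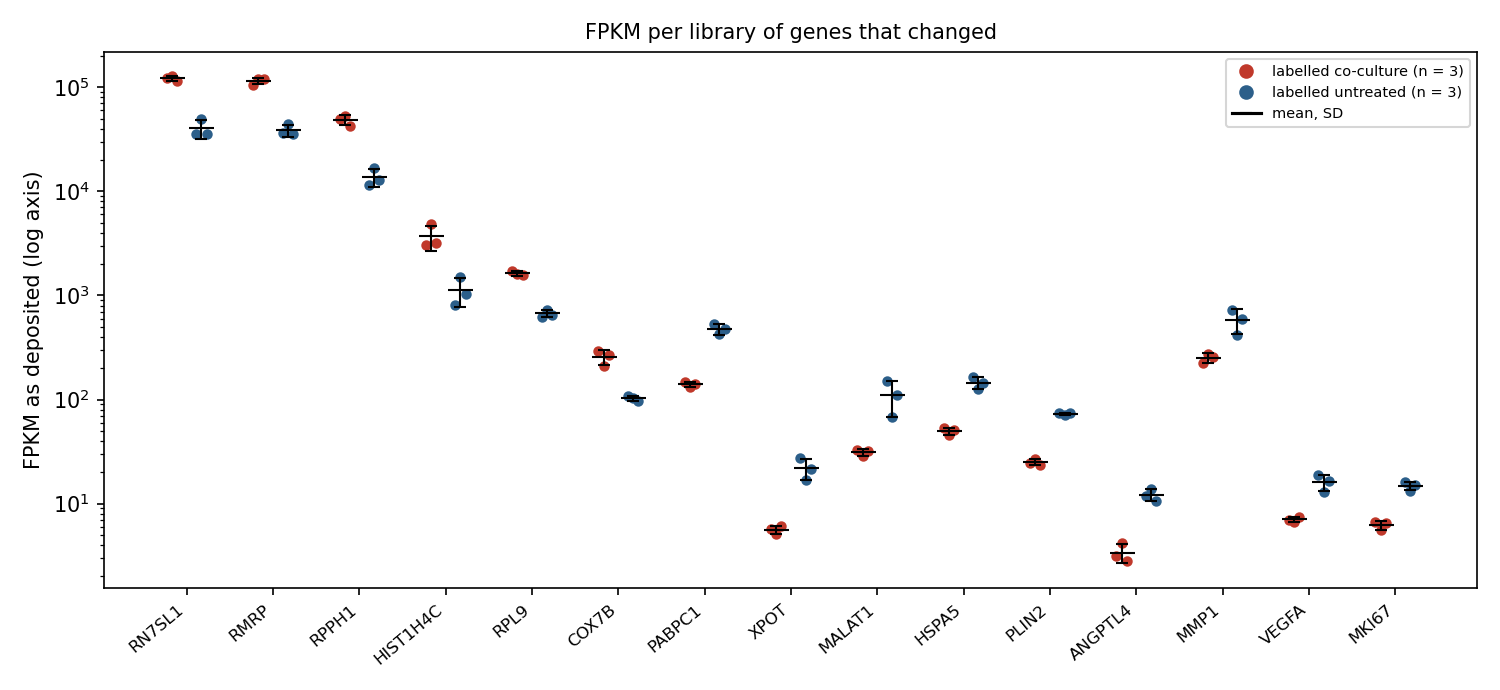
FPKM of 15 genes in each library (points, log axis) with the mean and SD of each group of 3. Small structural RNAs, HIST1H4C, RPL9 and COX7B lay higher in the libraries labelled co-culture, and PLIN2, ANGPTL4, HSPA5 and MMP1 lay lower.

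Small structural RNAs held the most abundant rises. RN7SL1, an RNA of the signal recognition particle (chromosome 14, 49586579 to 49586878, hg38), rose by 1.61 ± 0.195 (SE) with adjusted p = 8.58e-05, from 40318 ± 8217 to 121665 ± 7049 FPKM (mean ± SD, n = 3). RMRP, the RNA of the RNase MRP complex (chromosome 9, 35657750 to 35658018), rose by 1.59 (adjusted p = 6.72e-05, limma), and RPPH1, the RNA of RNase P (chromosome 14, 20343070 to 20343411), rose by 1.84 (adjusted p = 4.69e-05). Under TMM these changes were 2.06, 2.03 and 2.29. Quantile normalization cut them to 0.80, 0.45 and 1.16, and RMRP then did not pass (adjusted p = 0.18). RN7SL2, a near-identical copy of RN7SL1, rose by 1.54 (0.60 under quantile normalization). TERC, the telomerase RNA, rose from 1621 ± 191 to 4947 ± 612 FPKM (1.61, or 0.97 under quantile normalization). The largest rises among genes with a mean of at least 5 FPKM included the spliceosomal RNA copy RNVU1-4 (2.21, chromosome 1, 120912237 to 120955811), the ribosomal RNA gene RNA28S5 (2.01) and the U3 copies SNORD3B-2 (1.94) and SNORD3B-1 (1.85). MIR3648-1 rose as well, at 87.9, 34.7 and 69.4 FPKM against 16.9, not listed and 9.46 (adjusted p = 0.00457). MIR3648-1 and RNA28S5 share a locus on chromosome 21, 8197619 to 8411091, and these genes have near-identical copies, so reads could be split among them. Ribosomal RNA was depleted from these libraries, so values at that locus may reflect what depletion left rather than levels in the cells.

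RN7SK, the small nuclear RNA that holds back transcription elongation (chromosome 6, 52995619 to 52995951), was not listed in any of the 3 libraries labelled co-culture. In the libraries labelled untreated it stood at 168474, 201777 and 170977 FPKM, which was 22.7%, 23.4% and 22.9% of all FPKM listed. RNA45S5, the ribosomal RNA precursor (chromosome 21, 8433221 to 8446572), was likewise not listed in the libraries labelled co-culture and stood at 5545, 6698 and 5726 FPKM in the others. Both passed limma's test (adjusted p = 2.13e-15 and 2.64e-14), and no fold is given because the co-culture-labelled values are unlisted. RNA18S5 and RNA28S5, which are cut from that precursor, were listed in every library. They stood higher in the libraries labelled co-culture (822.6 against 349 and 502.4 against 125.2 FPKM). This argues against a true absence of RNA45S5, though depletion of ribosomal RNA may shape these levels. Whether RN7SK was absent or was left out of those files when they were made cannot be told from the values. If the files of the 2 groups were annotated or quantified differently, that would reach every gene value and the 6859 calls. Rescaling the libraries without the structural RNAs and histones left the median log2 change at −0.39.

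Apart from those RNAs, the largest falls were XPOT, the exporter of transfer RNA from the nucleus (−1.77 ± 0.155, chromosome 12, 64404372 to 64448683), PABPC1, the cytoplasmic poly(A)-binding protein (−1.75 ± 0.106, chromosome 8, 100702915 to 100722087), and STC1, a secreted glycoprotein hormone (−1.74 ± 0.306, chromosome 8, 23841920 to 23854807). Their adjusted p values were 3.86e-05, 1.92e-05 and 6.38e-04 (limma), and under TMM the falls were −1.37, −1.31 and −1.34. MALAT1, a nuclear long noncoding RNA (chromosome 11, 65497761 to 65506512), fell from 110 ± 41.6 to 31.0 ± 2.08 FPKM (−1.72, adjusted p = 1.20e-04, TMM −1.28).

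Lipid genes moved unequally. In the list of fatty acid uptake and lipid droplet genes, 1 of 21 tested genes rose and 9 fell, also when adjusted over the list alone, and its median of −0.18 turned to 0.25 under TMM, 0.08 under quantile normalization and 0.32 under median centring, with 10 genes higher and 6 lower under TMM. PLIN2 fell by 1.52 ± 0.09 (chromosome 9, 19115760 to 19127606, adjusted p = 1.92e-05, TMM −1.09). The acyl-CoA synthetases, which activate fatty acids, fell as well: ACSL5 by 1.31, ACSL4 by 1.15 and ACSL3 by 1.06 (TMM −0.90, −0.76 and −0.66). Of 23 PPAR targets and fatty acid oxidation genes, 1 rose and 14 fell, also adjusted over the list alone, with 7 higher and 8 lower under TMM. ANGPTL4 fell by 1.59 ± 0.143 (chromosome 19, 8364126 to 8374375, adjusted p = 3.86e-05, TMM −1.21), CAT, the peroxisomal catalase, by 1.16, and CPT1A, the gate of mitochondrial fatty acid entry, by 0.78 (TMM −0.36). FASN, the fatty acid synthase, did not pass (−0.17, adjusted p = 0.192), although it did with the replicate number as a block (adjusted p = 0.0398), and it stood higher under TMM (0.27, adjusted p = 0.0341) and median centring (0.33, adjusted p = 0.0151). HMGCS1, a cholesterol synthesis enzyme, stood at −0.28 (adjusted p = 0.111). Camera, limma's competitive list test, called neither list (adjusted p = 0.878 and 0.915).

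Among 24 tested inflammatory cytokine and NF-kB target genes, 18 fell and none rose, also adjusted over the list alone, and under TMM 9 fell and 2 rose. CSF3, the granulocyte growth factor, fell by 1.40 ± 0.169 (2.06 ± 0.644 against 7.04 ± 1.25 FPKM, adjusted p = 8.55e-05, TMM −1.06), NFKB1 by 0.98 and SOD2, the mitochondrial superoxide dismutase, by 0.93. IRAK2, an interleukin-1 receptor kinase, fell by 0.83, a call that quantile normalization and median centring ended (adjusted p = 0.0628 and 0.0517). IL6 fell by 0.92 ± 0.238 (1.94 ± 0.492 against 4.74 ± 1.87 FPKM, adjusted p = 0.00617), a call that TMM, quantile normalization and median centring ended (adjusted p = 0.0513, 0.142 and 0.145). CXCL8 differed by less than the spread between replicates (179 ± 111 against 194 ± 51.8 FPKM, adjusted p = 0.532), and CCL2 stayed below the filter, listed in co-culture replicate 3 alone (0.0553 FPKM) and at 0.188, 0.106 and 0.178 FPKM in the libraries labelled untreated. The camera test did not call the list (adjusted p = 0.312).

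Among 21 hypoxia response genes tested, 16 fell and none rose, also adjusted over the list alone, against 11 and 2 under TMM. ERO1A, which oxidizes thiols in the endoplasmic reticulum, fell by 1.28, the mitophagy receptor BNIP3L by 1.35, the oxygen sensor EGLN1 by 1.03 and VEGFA by 1.07 ± 0.134 (adjusted p = 9.86e-05, TMM −0.67). Camera gave the list an adjusted p of 0.107. All 3 libraries labelled co-culture lay below all 3 labelled untreated for these 4 genes. They were taken as called members with the smallest adjusted p, so this adds no support for the list.

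In the list of collagens and matrix proteins, 15 of 20 tested genes fell and none rose, or 18 when adjusted over the list alone, with 9 lower and 1 higher under TMM. LAMC1, a laminin chain, fell 2.3-fold (14.2 ± 1.29 against 34.5 ± 7.92 FPKM, adjusted p = 1.16e-04), and on the log2 scale COL4A1 fell by 0.86, COL8A1 by 0.84 and COL12A1 by 0.78. Of 20 matrix proteases and inhibitors, 17 fell and none rose, also adjusted over the list alone, with 10 lower and 2 higher under TMM. MMP1, the interstitial collagenase, fell by 1.17 ± 0.176 (251 ± 27.4 against 580 ± 155 FPKM, adjusted p = 2.48e-04, TMM −0.73), and the cell surface proteases ADAM17, ADAM9, ADAM10 and MMP14 fell by 1.18, 1.11, 0.85 and 0.78. VIM, the mesenchymal filament protein, fell by 0.71 (1989 ± 290 against 3232 ± 138 FPKM), a call that TMM and median centring ended (adjusted p = 0.0991 and 0.198). Camera called neither list (both adjusted p = 0.107).

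Leaving out 1 library mattered for a few single genes. The HMGCS1 log2 change passed only without co-culture replicate 2 (adjusted p = 0.0366), and the CXCL8 log2 change turned to 0.33 without that library.

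In the list of G2/M and mitosis genes, 23 of 36 fell and none rose, also adjusted over the list alone, with 18 lower and 7 higher under TMM. That share was near the 5986 of 10775 among all genes tested, and camera did not call the list (adjusted p = 0.107). PRC1, which bundles the microtubules of the central spindle, fell 2.3-fold (12.5 ± 1.4 against 30.1 ± 2.21 FPKM, adjusted p = 3.89e-05, TMM −0.78). On the log2 scale the kinesins KIF23 and KIF20A fell by 1.31 and 0.92, and BUB1, a spindle checkpoint kinase, by 1.21. MKI67, the Ki-67 proliferation antigen, fell by 1.14 ± 0.116 (6.22 ± 0.609 against 14.9 ± 1.43 FPKM, adjusted p = 4.90e-05, TMM −0.74). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, did not pass on the deposited scale (−0.03, adjusted p = 0.789) and was higher under TMM (0.41, adjusted p = 0.00337) and median centring (0.47, adjusted p = 0.00179).

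Of 25 ER chaperone and unfolded protein response genes, 20 fell and none rose, also adjusted over the list alone, with 12 lower and 3 higher under TMM. HSPA5 fell by 1.52 ± 0.113 (chromosome 9, 125234847 to 125241387, adjusted p = 3.46e-05, TMM −1.08), the lectin chaperone CANX by 1.39, and the disulfide isomerases PDIA3 and PDIA6 by 1.10 and 1.07. Of 20 heat shock genes, 17 fell and none rose, or 17 and 1 when adjusted over the list alone, with 9 lower and 3 higher under TMM. HSPA4, the mitochondrial chaperonin HSPD1, DNAJA1 and HSPH1 fell by 1.29, 1.25, 1.25 and 1.23. Camera gave adjusted p values of 0.0508 for the ER list and 0.0662 for the heat shock list.

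Histone, ribosomal protein and respiratory chain genes stood high against the other genes. All 18 tested replication-dependent histone genes rose, with a median of 1.23 (1.68 under TMM and 0.74 under quantile normalization, where 17 rose), and camera called the list (adjusted p = 1.03e-21, or adjusted p = 0.64 with an estimated correlation). HIST1H4C rose by 1.74 ± 0.228 (chromosome 6, 26103947 to 26104337, adjusted p = 1.24e-04), HIST1H3H by 1.65, HIST1H3A by 1.62 and HIST2H2BE by 0.87. Histone genes of this family have near-identical copies, so values of single members are uncertain. Of 76 cytosolic ribosomal protein genes, 47 rose and 8 fell (48 and 10 adjusted over the list alone; camera adjusted p = 5.89e-25, or 0.367 with an estimated correlation), with 65 higher and 1 lower under TMM but 19 higher and 24 lower under quantile normalization. RPL9 rose by 1.28 ± 0.103 (adjusted p = 3.86e-05), RPL39 by 1.08, RPS15A by 0.91 and RPL30 by 0.88, and many processed pseudogenes share reads with such genes. Among 46 nuclear-encoded oxidative phosphorylation genes, 20 rose and 13 fell, also adjusted over the list alone (camera adjusted p = 2.60e-08, or 0.367 with an estimated correlation), with 32 higher and 3 lower under TMM and 19 and 10 under quantile normalization. COX7B rose 2.47-fold (chromosome X, 77899463 to 77905384, adjusted p = 4.65e-05, TMM 1.75) and NDUFA4 by 0.76 on the log2 scale, whereas UQCRC2 and NDUFS1, large subunits of complexes III and I, both fell by 0.94 (TMM −0.52 for both). None of the 3 lists thus passed with an estimated correlation between genes.

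Other settings added lists to the 3 that camera called, each of them lower in the libraries labelled co-culture. After quantile normalization these were heat shock (adjusted p = 3.92e-04), G2/M and mitosis (0.00145), ER chaperone (0.00363), glycolysis (0.00363), protease (0.00569), YAP and TEAD target (0.0184), hypoxia (0.0435), autophagy (0.0435) and adipokine receptor genes (0.0454), while ribosomal protein and oxidative phosphorylation genes no longer passed (0.753 and 0.0905). Without untreated replicate 2 they were hypoxia (0.0357), protease (0.0351), collagen (0.0357), ER chaperone (0.0351), inflammatory (0.0467), stem cell (0.0467) and autophagy genes (0.0467), which makes 10 lists in place of 3. ER chaperone genes also passed without co-culture replicate 2 (0.0235) and without untreated replicate 1 (0.0452) or 3 (0.0467), and with 0.1 added to FPKM (0.0499). Heat shock genes passed without co-culture replicate 1 (0.0209). These calls rest on the preset correlation: with an estimated correlation, which was run on the deposited values of all 6 libraries alone, none of the added lists passed (adjusted p = 0.958 to 0.981).

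**Figure D2:**
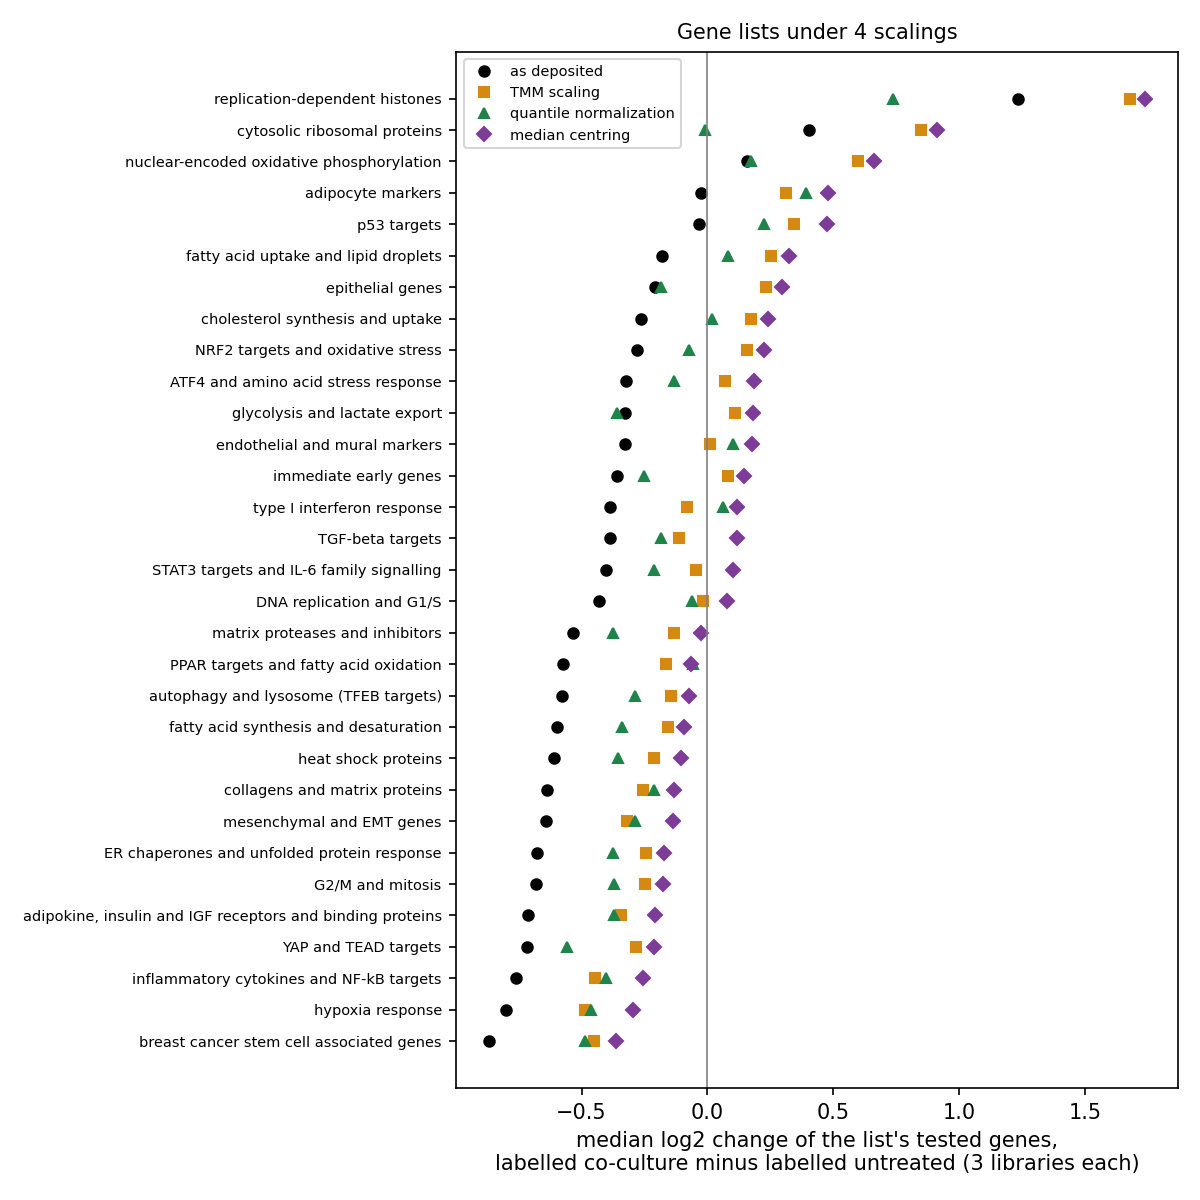
Median log2 change of the tested genes of 31 gene lists, co-culture-labelled minus untreated-labelled (3 libraries each), as deposited and under 3 other scalings (symbols). Histone genes lay highest under all 4 scalings, and ribosomal protein genes stood at −0.01 under quantile normalization.

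The other lists fixed before the data were examined passed no camera test on the deposited values of all 6 libraries, and most of their calls were falls. Stem cell associated genes had 9 of 11 lower and 0 higher (camera adjusted p = 0.107), receptors and binding proteins for adipokines, insulin and IGF 15 of 21 lower and 0 higher (0.157), and YAP and TEAD targets 15 lower and 1 higher of 21 (0.121). Autophagy and lysosome genes had 20 of 26 lower and 0 higher (0.107), mesenchymal and EMT genes 14 lower and 2 higher of 20 (0.323), and TGF-beta targets 14 lower and 1 higher of 21 (0.568). STAT3 targets had 10 of 18 lower and 0 higher (0.662), DNA replication and G1/S genes 22 lower and 1 higher of 39 (0.313), and fatty acid synthesis genes 9 lower and 1 higher of 15 (0.715). In each of these 9 lists the median was below 0 on the deposited scale and under TMM and quantile normalization, though median centring brought those of STAT3 targets (0.10), TGF-beta targets (0.12) and DNA replication genes (0.08) above 0. Adjusted over the list alone, the falls came to 10 stem cell genes, 21 autophagy genes and 15 EMT genes, and to the same numbers in the other 6 lists.

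Glycolysis genes had 12 of 22 lower and 0 higher, but 9 higher and 3 lower under TMM and 1 and 14 under quantile normalization (camera adjusted p = 0.915), and ATF4 stress genes had 17 lower and 1 higher of 29, but 10 higher and 6 lower under TMM and 5 and 8 under quantile normalization (0.98). For 9 further lists camera pointed up although the median and mean were below 0, because the test compares with other genes, whose median lay lower still or near it: fatty acid uptake, cholesterol synthesis (12 lower and 3 higher of 25, adjusted p = 0.484), NRF2 targets (11 and 3 of 23, 0.484), p53 targets (6 and 1 of 19, 0.312), epithelial genes (5 and 0 of 13, 0.915), immediate early genes (11 and 0 of 23, 0.98), interferon response genes (11 and 2 of 24, 0.98), and the markers of adipocytes and of endothelial and mural cells. Under TMM and median centring the medians of cholesterol synthesis, NRF2, p53, epithelial and immediate early genes lay above 0, and quantile normalization kept those of NRF2, epithelial and immediate early genes below it. The interferon list stood at −0.08 under TMM, 0.06 under quantile normalization and 0.12 under median centring. Adjusted over the list alone, 1 interferon gene in place of 2 was higher, and the other counts of these lists did not move. Fry, which asks whether the genes of a list move on balance in 1 direction, called 27 of 31 lists. Ribosomal protein and histone genes were called higher, and all other called lists lower. Fry does not compare with other genes. It was run on the deposited values, where the median of all genes tested was −0.388, so that shift alone can make a list pass as lower.

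Markers of other cell types served as a check for RNA from the adipose cells. The adipocyte genes ADIPOQ, RETN and CD36 and the stromal genes DCN and LUM were not listed in any library, and LEP reached at most 0.0151 FPKM. PLIN1, at 0.131, 0.0667 and 0.0565 FPKM in the libraries labelled co-culture, lay above its 0.0187, unlisted and 0.0162 FPKM in those labelled untreated, and FABP4 stood at 0.0444, unlisted and 0.139 FPKM against unlisted in all 3. LEP, CIDEA and AQP7 were listed in 1 library labelled untreated each and in none labelled co-culture. Other markers were well expressed in both groups, so they tell little of the adipose cells, among them ESAM (72.8 and 84.3 FPKM, co-culture-labelled and untreated-labelled), EGFL7 (71.3 and 54.8), PNPLA2 (54.4 and 56.6), CD68 (31.3 and 43.8) and MCAM (25.0 and 34.2). Of 6 adipocyte markers tested, CFD rose (2.88 ± 0.253 against 1.86 ± 0.0244 FPKM) and PPARG fell (10.91 ± 1.03 against 18.97 ± 3.66 FPKM, a call that the 3 other scalings ended), and camera gave an adjusted p of 0.189. Endothelial and mural markers had 1 higher and 3 lower of 6 tested (adjusted p = 0.878; 2 higher and 0 lower under TMM), stromal markers had 0 higher and 1 lower of 4, and immune markers 0 higher and 1 lower of 2, which is below the number camera needs. None of these counts moved when adjusted over the list alone. LEPR, the leptin receptor, was low and fell by 0.76 (0.691 ± 0.195 against 1.87 ± 0.47 FPKM), a call that median centring ended (adjusted p = 0.103). No gene of the mitochondrial genome was listed in the gene files.

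The lncRNA table asked the same question of assembled noncoding loci. PVT1 on chromosome 8 (127794480 to 128101595), a locus next to MYC, rose from 32.2 ± 1.69 to 68.9 ± 8.02 FPKM (1.09 ± 0.158, adjusted p = 0.0231), and SNHG8, a small nucleolar RNA host gene on chromosome 4 (118278762 to 118280126), rose from 198 ± 25.8 to 445 ± 64.3 FPKM (1.16 ± 0.206, adjusted p = 0.0402). MALAT1 on chromosome 11 (65497750 to 65506512) fell from 116 ± 44.7 to 33.0 ± 1.76 FPKM (−1.74 ± 0.269, adjusted p = 0.0242), and TUG1 on chromosome 22 (30969044 to 30980770) fell from 5.18 ± 0.329 to 1.53 ± 0.238 FPKM (−1.70 ± 0.266, adjusted p = 0.0244). A mitochondrial locus, XLOC_037571 (M, 2740 to 16569), fell from 1906 ± 553 to 416 ± 37 FPKM (−2.16 ± 0.285, adjusted p = 0.0202). This locus spans most of the mitochondrial genome, so its reads cannot be told from those of mitochondrial coding genes. Quantile normalization ended the calls of PVT1 (adjusted p = 0.158) and SNHG8 (0.352), and scaling by the gene medians that of TUG1 (0.058). With the replicate number as a block in limma, none of these loci passed. Adjusted p was then 0.0806 for PVT1, 0.0681 for SNHG8, 0.0867 for MALAT1, 0.110 for TUG1 and 0.0662 for XLOC_037571. NEAT1 and H19 were absent from this table. In the gene files, PVT1, SNHG8, MALAT1 and TUG1 stood at 0.812, 0.981, −1.717 and −1.295. There they did pass with the block (limma adjusted p = 1.61e-04, 3.44e-05, 8.09e-05 and 5.69e-05 in that order). Quantile normalization left PVT1 and SNHG8 at 1.229 and 1.055 in the gene files. These values come from the same libraries, so they are not separate evidence.

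Of 4641 lncRNA loci tested with limma, 50 were called, 32 higher and 18 lower. The unnamed locus XLOC_029976 (chromosome 6, 27295432 to 27295641) stood at 71.7, 17.9 and 95.3 FPKM in the libraries labelled co-culture and was listed at 0 in all 3 labelled untreated (adjusted p = 8.49e-04). XLOC_011094 (chromosome 14, 75222109 to 75222375) was likewise listed at 0 in those 3 and stood at 17.4, 35.4 and 2.84 FPKM in the others. XLOC_008127 (chromosome 12, 110404133 to 110404689) stood at 3.16, 4.35 and 2.86 FPKM against 0, 0.186 and 0.219 (adjusted p = 0.0298). A locus with the name of the coding gene PRKAR1A stood at 0, 1.17 and 0 FPKM against 5.77, 14.6 and 12.2 (adjusted p = 0.0402). Loci named for MYH11 and RPL14 fell by 3.08 and 2.26, and reads of those genes cannot be told from reads of the loci. Loci without a gene name had 25 higher and 2 lower of 3851, and loci with a name 7 higher and 16 lower of 790. In the gene files, 34 known lncRNAs were tested, with 8 higher and 10 lower, also adjusted over the list alone, but 17 higher and 8 lower under TMM.

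These 50 calls were fragile. With the replicate number as a block, 2 remained, both higher, XLOC_029976 among them (adjusted p = 0.0303), and no call was left without limma's variance trend (0 called, 486 at an unadjusted p under 0.05). Quantile normalization called 14 higher and 36 lower, and scaling by the gene medians 182 higher and 9 lower. The count fell to 22, 13 and 8 without co-culture replicate 1, 2 or 3, and to 1, 24 and 1 without untreated replicate 1, 2 or 3.

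The small-RNA libraries asked which miRNAs differed. In these libraries hsa-miR-7641 fell 9.31-fold, from 23.4 ± 4.3 to 2.5 ± 0.125 CPM (counts scaled to library size with TMM; mean ± SD, n = 3; −3.22 ± 0.242, adjusted p = 5.61e-05, edgeR). It had only 17, 18 and 17 reads in the libraries labelled co-culture, against 155, 173 and 126 in those labelled untreated. It was the only 1 of 485 miRNAs called, and 46 had an unadjusted p under 0.05. The most abundant, hsa-miR-21-5p, a miRNA raised in many tumours, took 30.7 ± 1.5% of miRNA reads in the libraries labelled co-culture and 36.3 ± 0.817% in those labelled untreated (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Its change of −0.45 ± 0.199 did not pass (adjusted p = 0.49).

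No label says that small-RNA libraries of the same replicate number shared a culture. Pairing by number was taken from residual correlations of these same counts (0.412, 0.597 and 0.311). With the number as a block edgeR called 59 miRNAs, 19 higher and 40 lower, 9 of them with at least a 2-fold change. DESeq2 with the same block called 17 and limma-voom 58. The blocked examples here were chosen after their values were seen, and all but hsa-miR-15b-3p passed in DESeq2 too. Over the 37 miRNAs picked for checks of other settings, some not mentioned here, the block added calls for 30 in edgeR but for 12 in DESeq2. Blocked edgeR errors were near equal for abundant miRNAs (0.103 for hsa-miR-126-3p, 0.106 for hsa-miR-32-5p and 0.109 for hsa-let-7a-5p). They thus appear to rest mostly on spread pooled over miRNAs, with 2 residual degrees of freedom, so the blocked p-values may be far too small. In the blocked edgeR fit hsa-miR-32-5p, a member of the family of miR-92, fell 2.29-fold (adjusted p = 2.25e-25, or 0.424 without the block), lower in all 3 pairs. Likewise hsa-miR-29b-3p, which targets collagen messages, fell by 0.76 ± 0.106, hsa-miR-142-3p, a miRNA of blood cells, by 0.83 ± 0.124, and hsa-miR-122-5p, the main miRNA of liver, by 1.18 ± 0.214, each lower in 3 of 3 pairs. In the same fit hsa-miR-21-5p fell by 0.44 (adjusted p = 0.00647), and hsa-miR-4521 rose from 1671 ± 431 to 2682 ± 149 CPM (0.72 ± 0.105, adjusted p = 3.58e-09). The passenger strands hsa-let-7a-2-3p and hsa-miR-15b-3p rose by 0.62 and 1.12. Not past the threshold in either fit were hsa-miR-210-3p, the hypoxia miRNA (−0.15 blocked, adjusted p = 0.463), hsa-miR-221-3p (0.25, 0.108), hsa-miR-146a-5p (−0.16, 0.335), hsa-let-7a-5p (0.21, 0.203), hsa-miR-126-3p (−0.14, 0.412) and hsa-miR-10b-5p (−0.09, 0.878), and hsa-miR-144-3p had too few reads to test. Unblocked, adding every miRNA with a read gave 7 calls, and keeping those with at least 100 CPM gave 0 (9 at an unadjusted p under 0.05).

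**Figure D3:**
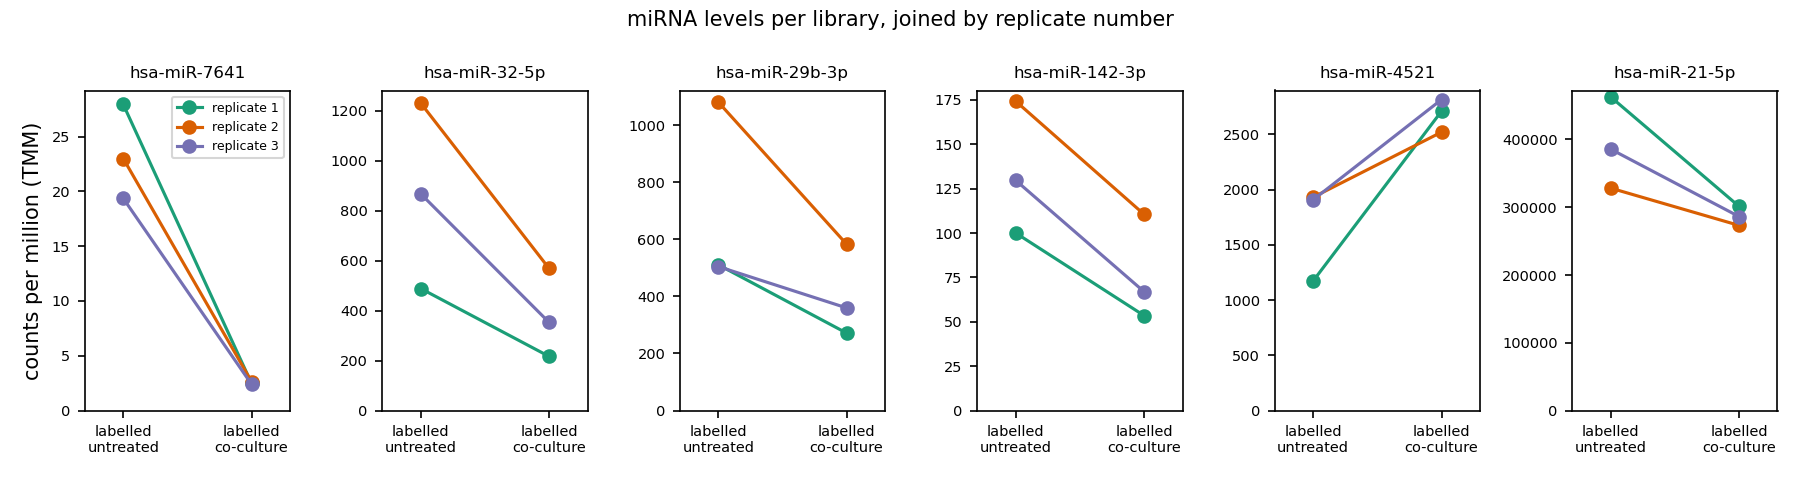
CPM (TMM) of 6 miRNAs in the libraries labelled untreated and co-culture, joined by replicate number. hsa-miR-7641, hsa-miR-32-5p, hsa-miR-29b-3p, hsa-miR-142-3p and hsa-miR-21-5p lay lower and hsa-miR-4521 higher in the libraries labelled co-culture in all 3 pairs.

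Of the 7 miRNA lists fixed before the data were examined, camera called 0, with 0 also under fry and with the block. Blocked member calls, higher and lower, were 0 and 1 of 6 for the EMT-restraining miR-200 and miR-205 family (camera adjusted p = 0.57), 3 and 1 of 18 for the let-7 family (0.534), 1 and 1 of 20 for miR-17-92 and paralogous clusters (0.153) and 3 and 3 of 28 for miRNAs tied to breast cancer invasion (0.534). They were 0 and 1 of 17 for hypoxia and inflammation miRNAs (0.947), 1 and 2 of 30 for adipocyte and mesenchymal miRNAs (0.534) and 1 and 3 of 11 for blood cell miRNAs (0.718). Adjusted over the list alone, the blocked calls were 0 and 2, 4 and 2, 1 and 1, 3 and 3, 0 and 0, 1 and 2, and 3 and 3 in that order, and 0 in every list without the block. The median and the test differed in sign for invasion miRNAs (median −0.003, test up), hypoxia miRNAs (0.009, test down without the block) and blood cell miRNAs (0.011, test down).

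A further comparison, added once the files showed circular RNA counts, asked which circular RNAs differed. More circular RNAs were listed in the libraries labelled co-culture (9787, 9970 and 10565) than in those labelled untreated (6662, 7392 and 6782), and the listed reads came to 2447700 ± 114400 against 1266090 ± 125400 (exact permutation p = 0.1 for both, two-sided, the smallest possible). A listed total holds only circular RNAs with at least 17 reads and is not the depth of a library. Within the listed reads, hsa_circRNA008217 of SPECC1 (chromosome 17, 20204333 to 20205912) fell by 2.37 ± 0.249, from 3978 ± 1134 to 768 ± 148 CPM (adjusted p = 0.00423, edgeR). A cadherin-family gene, FAT1, gave hsa_circRNA015143 (chromosome 4, 186706563 to 186709845), which fell by 2.25 ± 0.299 (adjusted p = 0.0213).

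Only 4 of 7685 circular RNAs tested with edgeR passed, all lower, and the count moved with the method: 153 with DESeq2 (60 higher and 93 lower), 30 with the replicate number as a block (17 and 13), 14 without a filter (7 and 7) and 1 among those listed in at least 5 libraries. The other 2 were hsa_circRNA015314 of NIPBL (chromosome 5, 36982165 to 36986301), with 802, 953 and 644 reads in the libraries labelled untreated, and hsa_circRNA010035 of ARHGAP35 (chromosome 19, 46918488 to 46937408), with 708, 237 and 568 reads, and neither was listed in any library labelled co-culture. Among the 1552 circular RNAs listed in all 6 libraries, 9 were called, 1 higher and 8 lower. In that set hsa_circRNA020446, named for CDR1 (chromosome X, 140783175 to 140784659), fell by 1.97 ± 0.282 (adjusted p = 1.56e-07), hsa_circRNA017368 of TULP4 by 2.39, hsa_circRNA004781 of FGD6 by 2.75, hsa_circRNA004699 of NAV3 by 2.53, hsa_circRNA014448 of APBB2 by 1.41 and hsa_circRNA014690 of AFF1 by 1.40, and hsa_circRNA002299 of DHTKD1 rose by 1.87 (adjusted p = 0.0424). The gene FPKM of the hosts of these falls fell as well, for example SPECC1 by 1.10 (TMM −0.70) and FAT1 by 1.11 (TMM −0.69). Gene FPKM may include reads of the circular RNAs themselves, so these falls are not a separate measure of linear RNA. The count of calls was 7 without co-culture replicate 3, and 9, 20 and 17 without untreated replicate 1, 2 or 3. Without co-culture replicate 1, the hsa_circRNA015143 log2 change (adjusted p = 0.105) and the hsa_circRNA010035 log2 change (adjusted p = 0.0608) no longer passed.

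**Figure D4:**
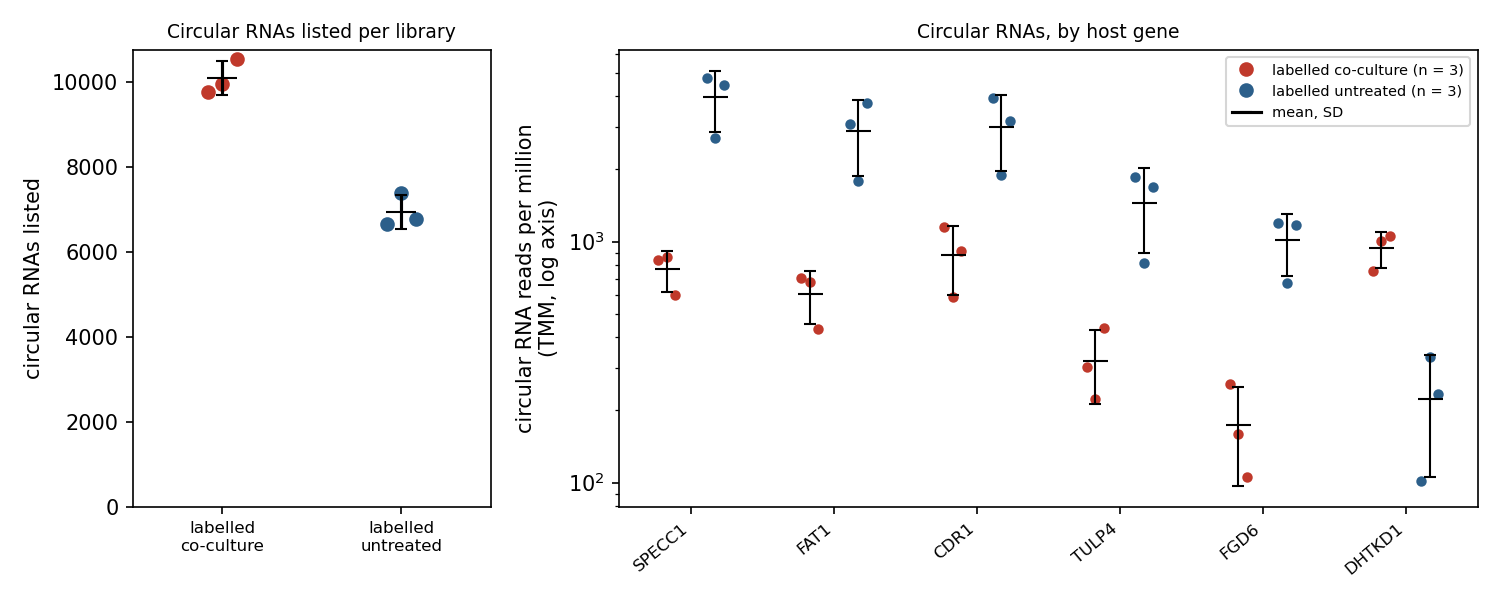
Left, circular RNAs listed per library; right, CPM (TMM) of 6 circular RNAs (log axis), with the mean and SD of each group of 3. All 3 libraries labelled co-culture listed more circular RNAs than any labelled untreated, and 5 of the 6 drawn circular RNAs lay lower in them.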

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

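The gene count of 6859 fell to 3972 with a mean of at least 5 FPKM and to 4373 when a change of 1.2-fold was required, was 7318 with the replicate block (6835 of them among the 6859), and was 5931 to 6897 with 1 library left out. Array weights gave 9432, with a warning that the weights had not converged. The lncRNA count of 50 was 33 with 1 added to FPKM, 78 with a mean of at least 1 FPKM, 191 when scaled by the gene medians, 0 without the variance trend, 2 with the replicate block, 3 among loci without a gene name and 1 to 24 with 1 library left out. Beside the 1 miRNA called, no filter gave 7, at least 100 CPM 0, the block 59, DESeq2 with the block 17 and limma-voom with the block 58, and each library left out gave 1. The circular RNA count of 4 was 9 among those listed in all 6 libraries, 1 in at least 5, 14 without a filter, 153 with DESeq2, 30 with the block and 3 to 20 with 1 library left out. Circular RNA libraries of the same number correlated at 0.028 or less, so that block has little ground. Gene libraries of the same number correlated at 0.124 to 0.298, but co-culture replicate 3 correlated more with untreated replicate 1 (0.232) than with its own number (0.194).

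The 3 gene lists called became 0 with an estimated correlation, 27 with fry, 10 after quantile normalization, 4 with 0.1 added to FPKM and 3 to 10 with 1 library left out. Among the 7 miRNA lists 0 passed in any setting.

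Directions turned as follows. The CXCL8 log2 change was 0.095 under TMM and 0.158 under median centring, and −0.793 to 0.33 with 1 library left out. The FASN log2 change was 0.27 and 0.334 under the same scalings, and the HMGCS1 log2 change 0.079 and 0.221, with 0.249 under quantile normalization. The CDKN1A log2 change was 0.407 and 0.474, with 0.124 under quantile normalization and −0.084 to 0.008 with 1 library left out. Without TMM, the hsa-miR-210-3p log2 change was 0.017, the hsa-miR-10b-5p log2 change 0.092, the hsa-miR-146a-5p log2 change 0.031 and the hsa-miR-126-3p log2 change 0.052. With 1 library left out, the hsa-miR-210-3p log2 change was −0.258 to 0.028.

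Of 1357 comparisons over 72 named genes, 1330 kept the main result, and so did 90 of 203 over 14 named lncRNA loci (the other 113 lost their call), 457 of 538 over 37 named miRNAs and 90 of 128 over 11 named circular RNAs. Here the named loci and miRNAs include some that were picked for these checks but are not mentioned in the text. Among the named genes the block changed the call of FASN alone. It ended those of 13 named lncRNA loci and added those of 30 named miRNAs and of 6 named circular RNAs, from CDR1, TULP4, FGD6, NAV3, APBB2 and DHTKD1. The planned use of the files called TPM in place of FPKM was not run, because they hold circular RNAs, and the miRNA alternatives for values other than counts did not apply.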

Other observations

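Of the tests below, those on locus span, on the raised minimum of circular RNA reads and on host genes were written before their values were seen, and those on quantile normalization, exchanged labels and regrouped libraries were chosen after seeing results. The quantile test also carries a limit, a list making up at most 20% of the genes at its level, that was set after its values were seen, and this limit is why the ribosomal protein result counts as undecided. Also set after values were seen were the reasons for leaving the respiratory chain result and the circular RNA read total open.

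Families of genes with a shared symbol stem, added after the fixed lists, gave further groups. Eukaryotic translation initiation factors (EIF) had 2 higher and 39 lower of 51 tested (10 and 23 under TMM; camera adjusted p = 0.0357, or adjusted p = 0.447 with an estimated correlation). Ubiquitin-specific proteases (USP) had 0 higher and 31 lower of 38 (3 and 19 under TMM; adjusted p = 0.0169, or 0.831 with an estimated correlation). Mitochondrial ribosomal proteins of the large subunit (MRPL) had 13 higher and 13 lower of 49, but 30 and 3 under TMM (adjusted p = 5.11e-06, or 0.447 with an estimated correlation), whereas those of the small subunit (MRPS) had 8 higher and 11 lower of 29, or 16 and 5 under TMM, and did not pass (0.0506, though 0.0496 with the replicate block). Small structural RNAs had 37 higher and 3 lower of 46 (adjusted p = 3.65e-31, or 0.209 with an estimated correlation). None of the 64 families passed with an estimated correlation.

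Changes also differed with gene structure and level. Over 5 equal groups of genes, from the shortest to the longest loci, the median log2 change was −0.022, −0.245, −0.434, −0.562 and −0.622. From the least to the most abundant genes it was −0.448, −0.558, −0.515, −0.325 and −0.059, rising at every step after the first. In the same order 46, 61, 71, 184 and 511 genes were called higher, and 1305, 1426, 1348, 1141 and 766 lower. RNA integrity, fragment selection or library preparation that differed between the groups could make such differences, and no file measures them.

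Ribosomal protein, respiratory chain and histone genes stood high against other genes, though camera called none of these lists with an estimated correlation (adjusted p = 0.367, 0.367 and 0.64). Short locus span alone may not account for the first 2: their medians lay at percentile 100 and 99.83 of 10000 random lists matched on span and FPKM, though matched genes for ribosomal proteins had a median of 574.8 FPKM against 1030, and transcript length was not tested. After quantile normalization the camera adjusted p was 0.753 for ribosomal proteins, 0.0905 for respiratory chain genes and 1.22e-06 for histones, all with the preset correlation, since an estimated one was not run there. Scaling that depends on abundance may not account for histones, of which 17 of 18 still rose then. It stays open for ribosomal proteins, which are 46.9% of the genes at their level, and for respiratory chain genes. The median log2 change of respiratory chain genes was 0.157 (quartiles −0.329 and 0.567) as deposited and 0.173 (−0.191 and 0.504) after quantile normalization. Their call ended there, while the median of all genes moved from −0.388 to −0.008. Higher histone messages could reflect more cells in S phase, but DNA replication genes were not higher, or retention of messages without poly(A) tails, which the files cannot separate.

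More circular RNAs were listed in the libraries labelled co-culture. Raising the minimum in those libraries from 17 to 33 reads left at least 9366, above the highest other library at 7392, but circular RNAs found in 1 library only had a median of 167 reads, so the minimum hardly governs what is listed and a larger read total stays open. Hosts of circular RNAs listed only in libraries labelled co-culture had a median TMM change of −0.26 (bootstrap interval −0.283 to −0.231), so as a set they were not higher. This lay above the −0.323 (−0.366 to −0.277) of hosts of circular RNAs listed only in the other libraries, the order that higher host levels would give. The intervals resample host genes and not libraries. Higher linear levels of the host genes are thus not shown, and they are not excluded. These host values are gene FPKM and may include circular RNA reads. Long-RNA depth and RNase or depletion steps are not given and could differ.

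PLIN2 and ANGPTL4, which free fatty acids induce in many cells, were lower in the libraries labelled co-culture. The codes of the data columns raise the possibility of exchanged labels, which might explain this, although the sample titles go with the treatment labels, and the camera adjusted p of the PPAR target list, 0.915, does not decide it. The adipocyte genes PLIN1 and FABP4 lay higher in the libraries labelled co-culture and LEP in those labelled untreated, all at under 0.14 FPKM, too low to decide it either. A nutrient or stress difference between the cultures is another possibility, and neither can be separated from the other with these files.

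Regrouping the 6 libraries gives only 10 splits into 3 and 3, too few to test the counts. The real split called 6859 genes, 50 lncRNA loci, 1 miRNA and 4 circular RNAs, against at most 1, 3, 0 and 0 in any other, so 1 split of 10 reached each real count. For the gene lists, 10 of 10 splits reached the real count of 3, with up to 14 called in another, so camera's preset correlation may be too small for these lists. For the miRNA lists the real count was 0, which any split must reach, so regrouping decides nothing there (at most 1 called in another).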
